A study of Mus musculus with 165 samples.

How the data were processed

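Chromosome compartments were studied by in situ Hi-C, which cross-links and ligates DNA that lies close together in the nucleus and reads the ligated pairs. The cells were ECOMG cells, mouse myeloid progenitors of C57BL/6 origin that depend on GM-CSF and are kept undifferentiated in the presence of estradiol. Per the labels' protocols, they became neutrophils over 5 days without estradiol. Neutrophils were activated with the calcium ionophore A23187, which carries calcium across membranes, at 20 uM in medium brought to 1 mM calcium chloride.

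The series lists 165 samples, of which 17 are Hi-C libraries. The other 148 (ChIP, ATAC and GRO libraries and inputs) were not analysed here. The 6 deposited files are 4 tracks of the first principal component (PC1) of the Hi-C matrix, and lists of positive and of negative domains of the untreated neutrophil track. The progenitor track is a pool of 7 libraries per the labels. The untreated neutrophil track is a pool of 8 libraries from 7 replicates, 1 of which was amplified in separate PCR replicates. The 15 min and 30 min tracks belong to 1 sample each, and whether either holds more than 1 library is not given in the sources used here.

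The PC1 values are scores without a unit, made by the authors with HiC-Pro, Bowtie2 and HOMER on the genome build mm9, per the submitters' processing notes. Versions and settings of these tools are not given in the sources used here. The deposited values are spaced at 25 kb, and the file titles give windows of 50 kb, so neighbouring bins share reads. On every chromosome the values had a mean of 0 and an SD of 1.00, so that the zero is the chromosome's own mean and a change in the overall strength of compartments on a chromosome cannot be read from them. The domain scores, as deposited by the authors, equalled the mean PC1 of the untreated track over the domain to within 0.001 in all 1486 positive and 1576 negative domains. Positive values are called compartment A here and negative values compartment B, after the usual convention for active and inactive chromatin. Whether the sign follows gene density on each chromosome was not tested here. Pearson r over bins was above 0.85 for every pair of tracks on every chromosome, so signs run the same way in all 4 tracks.

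The number of reads behind each track is unknown, since the values carry no counts. No interval or detection floor that needs counts is given. Each group has 1 track, so no difference has a replicate check, no p-value is given, and the spread stated is the range over chromosomes, which are not replicates. Per the labels, progenitor and untreated libraries were sequenced on 1 instrument model and activated libraries on other models, without saying which model served which time. The labels also mark every progenitor and untreated library as a re-analysis, and the activated libraries not. Between untreated and activated cells, treatment therefore cannot be told apart from sequencing batch. The same holds for any other difference between the re-analysed and the activated libraries. Progenitor against untreated and 15 min against 30 min each lie within 1 described protocol. The 15 min sample is labelled replicate 2 and the 30 min sample replicate 1, so time goes with replicate in that comparison.

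Bins with a non-zero value in all 4 tracks on 20 chromosomes (1 to 19 and X) were used. This left 100644 bins, or 2516 Mb, of the 101351 found in any track. The 8 bins of the Y chromosome were not used. A chromosome was to be left out where r between any pair of tracks was under 0.5, and 0 were. A bin was called switched where its PC1 changed sign, the change was at least 0.5 times the root mean square of the first track, and it lay in a run of at least 2 neighbouring bins that did so in the same direction. The contrast between compartments was the mean PC1 over bins in the untreated A domains minus that over bins in the untreated B domains. Regions named in the text were taken from the 5 longest runs B to A and the 5 longest A to B of each comparison, ties going to the larger mean change, and are described in order of length. Switched-bin rule, contrast, covariances, regions and most alternatives were fixed before the data were examined. Coordinates are 1-based mm9 positions.

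The switch rule was tested on simulated data of 100644 bins. The truth was a running mean of the untreated track over 5 bins, and noise was taken from the difference of the activated tracks. Regions of 10 bins were given a change of 0.7 (78 regions), 1 (200 regions) or 1.5 PC1 units (200 regions) across zero. Of their bins, 72.7%, 94.2% and 99.8% were called. Of the unchanged bins, 0.977%, 1.03% and 0.941% were called in those 3 simulations. The running mean smooths short segments, so these shares may not hold for the untreated track as it is. Since comparisons with the untreated track share it, 50 sets of unchanged tracks were also simulated, built on a mean over tracks. They give the overlap and covariance that this noise alone makes against a shared untreated track. That noise holds any real difference between the activated tracks, and noise of the untreated track above it is left out.

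Alternatives were scaling by root mean square per chromosome, quantile normalization to the untreated track, other size and run limits, even-numbered or odd-numbered bins alone, autosomes alone, other definitions of A and B bins, and the median. A moved zero and a running mean over 5 bins were chosen after seeing the data. The 15 gene lists fixed at the start were not used, because gene positions on mm9 were not used here, and coordinates were not converted from another build. The planned median changes of gene lists and the naming of genes within regions are therefore not reported. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.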

Results

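PC1 tracks of in situ Hi-C were compared between myeloid progenitors, neutrophils derived from such cells, and neutrophils after 15 or 30 min with A23187. The labels mark the progenitor and untreated libraries as re-analysed, and the activated ones not. The series set out to learn how calcium signalling alters nuclear architecture. The 4 tracks held values for 101003 (progenitor), 101046 (untreated neutrophil), 100783 (15 min) and 101298 bins (30 min), and 100644 were compared. Compartment A took 42.7% of the bins in progenitors, 41.6% in untreated neutrophils, 46.7% at 15 min and 44.3% at 30 min. Over bins, which are not independent replicates, Pearson r was lowest for progenitor against untreated neutrophil (0.945) and highest for progenitor against 30 min (0.968). It was 0.954 for progenitor against 15 min, 0.960 and 0.953 for untreated against 15 min and 30 min, and 0.965 between the activated tracks. The untreated track had the most sign changes between neighbouring bins, 3743 against 2799 in progenitors, 3077 at 15 min and 2307 at 30 min. Its median B segment measured 325 kb, and the median was 450 kb in progenitors, 425 kb at 15 min and 550 kb at 30 min. Median A segments measured 225 kb in progenitors, 250 kb in untreated neutrophils, 275 kb at 15 min and 387.5 kb at 30 min. Noise in a track can add sign changes and shorten segments. The local noise variance, defined further below, was highest in the untreated track (0.0218) and lowest at 30 min (0.00595). Whether these differences lie in the cells was not tested. No difference below has a replicate check, because each group has 1 track.

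The first comparison asked which regions changed compartment as progenitors became neutrophils. More of the genome went from A to B than from B to A: 3154 bins in 509 runs (3.13%) against 1655 bins in 430 runs (1.64%). Regions that left A were also longer, with 92 of them spanning at least 10 bins against 24 of those that entered A. Chromosomes 6 and 13 lost most, with 7.16% and 6.05% of their bins going from A to B, and the lowest share was 1.13%, on chromosome 5. The A share fell on 15 of the 20 chromosomes. On 3 chromosomes more bins went from B to A than from A to B: X (3.11% against 1.51% of its bins), 11 (79 against 70 bins) and 18 (46 against 41 bins).

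The longest region lost from A in differentiation lay on chromosome 14, from 24375001 to 25225000 (850 kb), where mean PC1 went from 0.259 in progenitors to -0.423 in neutrophils. On chromosome 6, 116775001 to 117600000 went from 0.452 to -0.441. The largest change among the 5 longest was on chromosome 7, from 131400001 to 132125000, where PC1 went from 0.714 to -0.816. On chromosome 2, 74700001 to 75375000 went from 0.433 to -0.535, and on chromosome 15, 17525001 to 18175000 went from 0.370 to -0.400. In the other direction, chromosome 1 from 144675001 to 145450000 (775 kb) went from -0.502 to 0.701. Chromosome X from 14350001 to 14900000 went from -0.282 to 0.691, and chromosome 13 from 88350001 to 88850000 went from -0.918 to 0.338. On chromosome 2, 79700001 to 80125000 went from -0.376 to 0.650, and on chromosome X, 55250001 to 55650000 went from -0.397 to 0.351. These bins carry no count, so the error of a single region is not known.

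The next comparison asked what 15 min of A23187 did to the compartments of neutrophils. Nearly all switches went into A, 3308 bins in 660 runs (3.29%) against 229 bins in 64 runs (0.228%) in the opposite direction. A simulated unchanged track gave 459 and 453 bins, so the calls from A to B were fewer than that noise alone makes. The A share was higher at 15 min on 20 of 20 chromosomes, by a median of 5.42 percentage points (range 1.16 to 8.24). Chromosome 6 switched most, with 5.95% of its bins going from B to A and 0 going from A to B. Many of the switches into A were flips of whole B segments: 238 segments flipped over at least 90% of their length and held 47.1% of these bins. Of the 1572 untreated B domains with bins in this comparison, 378 had a mean above zero at 15 min, and they made up 60.4% of the domains shorter than 250 kb and 11.1% of the longer ones. Of the 1482 A domains, 45 had a mean below zero. Segments and domains were defined on the untreated track, so noise in it alone could flip short ones more often.

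At 15 min the longest region that entered A was the stretch of chromosome 14 lost in differentiation, 24375001 to 25225000, which stood at 0.258 beside 0.259 in progenitors. On chromosome 3, 101875001 to 102475000 went from -0.554 to 0.389, and on chromosome 6, 49375001 to 49975000 went from -0.431 to 0.278. On chromosome 1, 60525001 to 61075000 had the largest change of the 5 longest, from -0.361 to 0.929, and chromosome 7 from 151100001 to 151600000 went from -0.481 to 0.169. The longest region that left A was on chromosome 8, 130675001 to 131075000 (400 kb), from 0.516 to -0.496. Chromosome 12 from 93600001 to 93925000 went from 0.515 to -0.321, and chromosome 13 from 82975001 to 83175000 went from 0.617 to -0.359. When bins were grouped into 10 by their progenitor PC1, those of intermediate level gained at 15 min (0.175 in group 6 and 0.162 in group 7). Both ends moved down (-0.0962 in the lowest group and -0.158 in the highest). Each chromosome has a mean of 0 in every track, so a gain in some groups has to be offset by a fall in others. The fall at the ends is therefore no separate result. With the values quantile-normalized to the untreated track, which forces every track to hold the same number of positive bins, 48.0% of the switched bins went from B to A in place of 93.5%, with 858 bins against 930.

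At 30 min the direction was again mostly into A, with 2816 bins in 523 runs (2.80%) against 833 bins in 248 runs (0.828%). Switches out of A were thus more numerous than at 15 min. They were also above the 453 bins of the simulation. That simulation leaves out extra noise of the untreated track, so no excess over noise is read from this. The A share was higher than in untreated cells on 19 of 20 chromosomes (median 2.96 percentage points, range -1.66 to 7.19), chromosome 11 being the exception. Chromosome X had the highest share of bins going from B to A (6.16%), followed by chromosome 13 (5.06%). Whole B segments carried most of the change, 279 of them holding 61.2% of the bins that entered A. Of the untreated B domains 359 had a mean above zero, and 157 of the A domains had a mean below it, against 45 at 15 min. Quantile normalization to the untreated track took the B to A share of switched bins from 77.2% to 52.5%, with 1690 bins against 1526.

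The longest region that entered A at 30 min was on chromosome 1, 55450001 to 56200000 (750 kb), from -0.437 in untreated neutrophils to 0.415, with -0.286 at 15 min. On chromosome X, 139925001 to 140650000 went from -0.253 to 0.531 and 137775001 to 138475000 from -0.358 to 0.412, and both were below the untreated value at 15 min (-0.531 and -0.488). Chromosome 12 from 100300001 to 100925000 went from -0.411 to 0.716, and chromosome 4 from 7225001 to 7775000 went from -0.261 to 0.597. The longest region that left A was the one gained in differentiation on chromosome 13, 88350001 to 88850000, which went from 0.338 to -0.820, beside -0.918 in progenitors. Chromosome 12 from 93600001 to 93925000 stood at -0.384, near its value at 15 min (-0.321). The stretch of chromosome 14 that had entered A at 15 min, 24375001 to 25225000, was at -0.216 at 30 min.

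**Figure D1:**
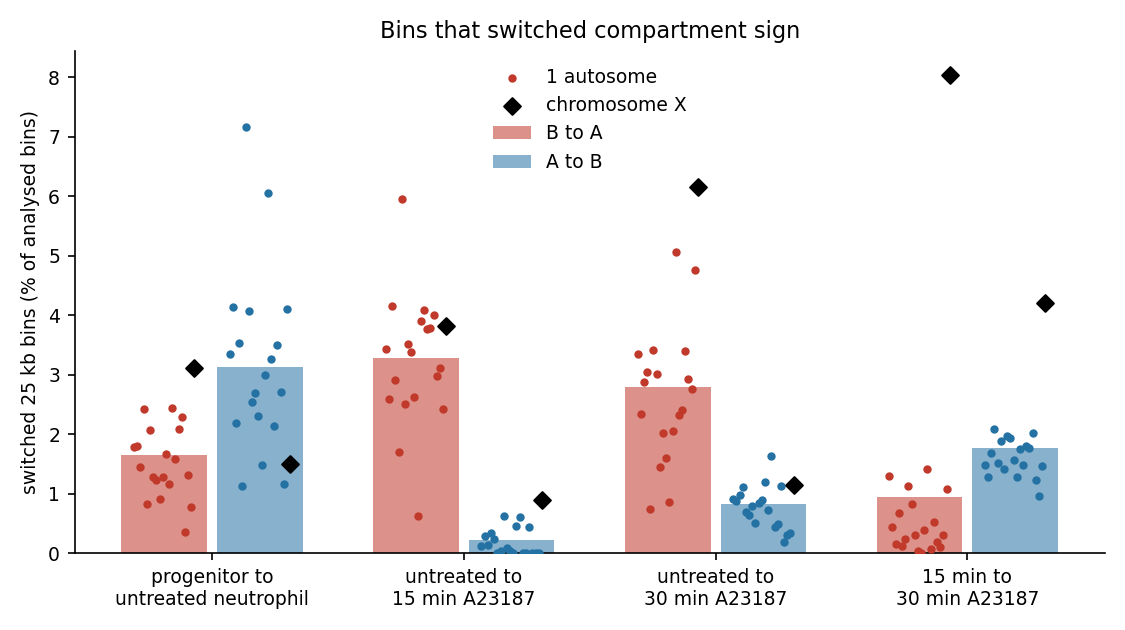
Switched 25 kb bins as a percent of analysed bins (y axis) in each comparison (x axis), B to A in red and A to B in blue. Bars give all 20 chromosomes together, dots single autosomes and black diamonds chromosome X. At 15 min the bars stand at 3.29% and 0.228%, and chromosome X reaches 8.04% between 15 and 30 min.

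**Figure D2:**
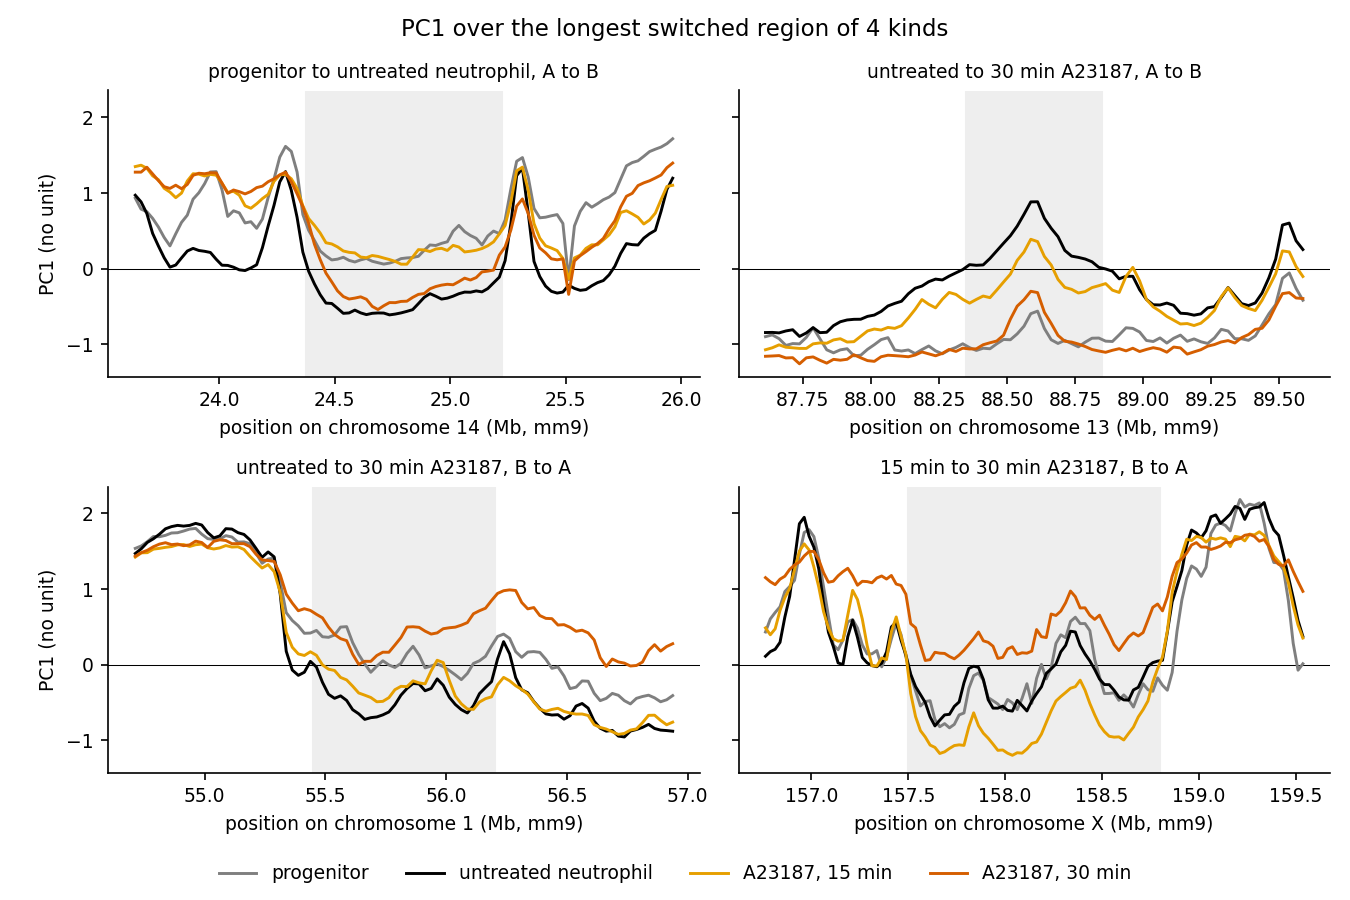
PC1 (y axis, no unit) along mm9 position (x axis, Mb) for the 4 tracks around the longest switched region of 4 kinds, which is shaded. On chromosome 14 the 15 min track lies at 0.258 and the progenitor track at 0.259 on average over the shaded region, and on chromosome X the 30 min track is the only one with a mean above zero over the shaded region (0.390).

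The times shared 1251 bins that went from B to A, which is 37.8% of those at 15 min and 44.4% of those at 30 min. Independent lists of these sizes drawn from all bins would share 92.6 bins. This baseline and the one for A to B below are too low, since both lists can hold only bins of the same sign in the untreated track. Unchanged simulated tracks against a shared untreated track had shorter lists, of 459 bins on average, and shared 26.8% of them (range 14.1 to 39.1%). Such shares depend on list length, so no excess is read from them. For A to B, 106 bins were shared, 46.3% of those at 15 min and 12.7% of those at 30 min. Independent lists would share 1.90, and the simulated lists of 453 bins shared 37.3% (range 25.5 to 49.8%). No bin switched in opposite directions at the 2 times, as the rule requires a common starting sign. The covariance of the PC1 changes was 0.0530 and the simulated one 0.0352, a gap of 0.0177. The simulation leaves out noise of the untreated track above that between the activated tracks. Such noise would also make a gap, so no common response is read from it. Part or all of the overlap and of the gap may come from the shared untreated track, which could not be split.

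The 15 min sample is labelled replicate 2 and the 30 min sample replicate 1, so time and replicate cannot be told apart between them. Between 15 and 30 min, the tracks differed more out of A than into it: 1780 bins in 446 runs (1.77%) went from A to B and 945 bins in 144 runs (0.939%) from B to A. The A share was lower at 30 min on 18 of 20 chromosomes. Chromosome X stood apart, with 8.04% of its bins going from B to A, where chromosome 13 came next with 1.42%, and 4.21% going from A to B. Its r between the times was 0.856 and that of the lowest autosome 0.963. Without chromosome X the share of bins that went from B to A was 0.501%. With quantile normalization 1253 bins went from B to A and 820 from A to B, so that the B to A share of calls was 60.4% in place of 34.7%.

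The longest run between the times was on chromosome X, 157500001 to 158800000 (1300 kb), at -0.811 at 15 min and 0.390 at 30 min, with -0.273 in untreated cells. In the opposite direction, chromosome X from 151850001 to 152725000 (875 kb) was at 0.744 at 15 min and -0.556 at 30 min, with 0.0125 in untreated cells. Outside X, chromosome 1 from 56000001 to 56650000 went from -0.501 to 0.631. Chromosome 8 from 16150001 to 16600000 went from 0.313 to -0.672, chromosome 6 from 49500001 to 49950000 from 0.214 to -0.393, and chromosome 4 from 13300001 to 13725000 from 0.422 to -0.713. Of the 5 longest runs from B to A, 4 lay on chromosome X.

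**Figure D3:**
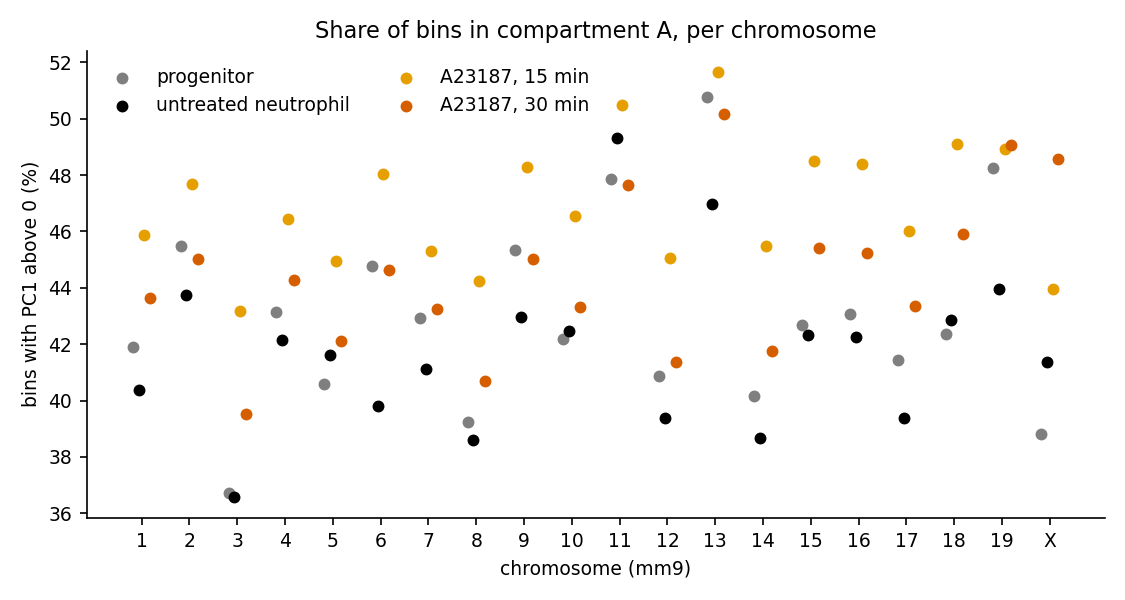
Percent of bins with PC1 above zero (y axis) on each chromosome (x axis), 1 point per track. The 15 min point is above the untreated one on 20 of 20 chromosomes, and the 30 min point on 19 of 20.

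**Figure D4:**
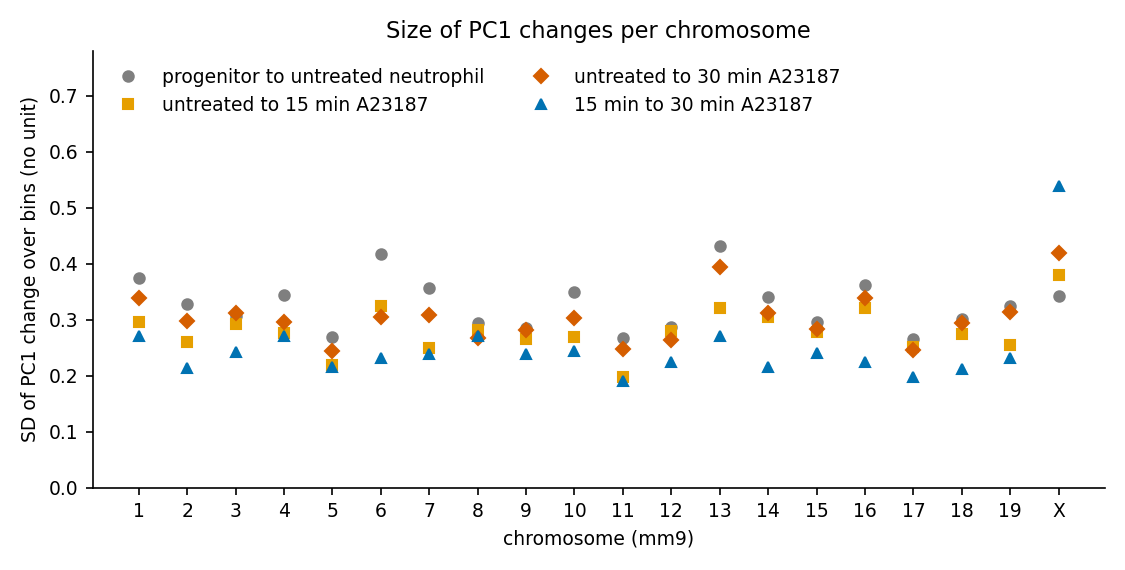
SD over bins of the PC1 change (y axis, no unit) on each chromosome (x axis) in the 4 comparisons. Between 15 and 30 min chromosome X reaches 0.538, and the highest autosome 0.271.

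A further comparison set activation against differentiation, bin by bin. Of the 3154 bins that left A in differentiation, 1589 (50.4%) were called switched back to A at 15 min and 1577 (50.0%) at 30 min, 943 of them at both. By sign alone, without the size and run limits, 2132 (67.6%) and 2009 (63.7%) of them were above zero. Independent lists drawn from all bins would give 104 and 88.2 bins called back. These baselines and those for the other direction are too low, since both lists can hold only bins of the same sign in the untreated track. In the simulation of unchanged tracks 27.7% of a list of 446 bins came back (range 16.7 to 44.6%). Of the 1655 bins that entered A, 129 (7.79%) were called switched back to B at 15 min and 461 (27.9%) at 30 min, beside 3.77 and 13.7 for independent lists. The simulated share was 37.4% of 448 bins (range 21.6 to 46.6%). The activation lists were longer than the simulated ones for B to A, and held only 229 bins for A to B at 15 min, so observed and simulated shares cannot be ranked. Of the bins that went from A to B, 56.3% at 15 min and 55.3% at 30 min were such returns, and of those that went from B to A, 48.0% and 56.0%. By sign alone, 313 (18.9%) and 729 (44.0%) of the 1655 bins that entered A in differentiation were below zero at 15 min and 30 min. Among the 92 long regions lost from A, 57 had a mean above zero at 15 min and 54 at 30 min. Among the 24 long regions gained, 5 and 9 had a mean below zero. The covariance of the differentiation change with the activation change was -0.0500 at 15 min and -0.0711 at 30 min, against -0.0354 from the shared untreated track in the simulation. The untreated track enters both changes with opposite signs, so excess noise in it would make the same pattern. A local noise variance was taken from each bin's deviation from the mean of the bins 50 kb to either side. It was highest in the untreated track, at 0.0218, against 0.0134 in progenitors, 0.0121 at 15 min and 0.00595 at 30 min. This estimate may also hold real fine structure.

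Compared directly with progenitors, a comparison the untreated track does not enter, 15 min cells had 3268 bins that were A in place of B and 620 that were B in place of A. At 30 min these were 1949 and 899. Of the 3154 bins lost from A in differentiation, 475 (15.1%) were also switched from A to B between progenitors and 15 min cells and 709 (22.5%) between progenitors and 30 min cells. Of the 1655 gained bins, 1127 (68.1%) and 660 (39.9%) were also switched. These 4 shares are over bins chosen by their switch in the untreated track, so excess noise in that track alone would lower them.

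The mean difference in PC1 between the untreated A and B domains was 1.78 in progenitors, 1.87 in untreated neutrophils, and 1.83 at both times of activation. It was 5.06% higher in neutrophils than in progenitors (range over chromosomes 2.41 to 9.95%), and the change was -2.41% at 15 min and -2.41% at 30 min. The domains were called on the untreated track, which favours that track. With bins taken by a common sign in all 4 tracks the changes were -0.346%, 1.20% and 1.52%, so no direction of this contrast holds across definitions.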

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

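The tests against sequencing batch, with the share of chromosomes they ask for, and against a deviation of the untreated track were chosen only after the result was seen, as were the moved zero and the choice of patterns.

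Among the 29 longest regions of the comparisons with activated cells and the A shares of the 20 chromosomes, 14 had changes from the untreated track with opposite signs at 15 and 30 min. Regions from the comparison of 15 with 30 min were chosen because PC1 changed sign between those tracks. That choice favours opposite signs and large differences. The differences are given as the 30 min change minus the 15 min change, and none was tested, since each time has 1 track. The A share of chromosome 11 rose by 1.16 percentage points at 15 min and fell by 1.66 at 30 min, a difference of -2.82. On chromosome X, the difference in mean PC1 was 1.11 over 49750001 to 49975000 and 0.875 over the longer 49250001 to 49975000. It was 1.06 over 139925001 to 140650000 (1.07 to 140625000), and 0.900 over 137775001 to 138475000 (0.902 from 137800001). Also on X it was 1.20 over 157500001 to 158800000 and -1.30 over 151850001 to 152725000. On autosomes it was 1.37 over chromosome 8, 128000001 to 128200000, and 1.13 over chromosome 1, 56000001 to 56650000. It was -0.985 over chromosome 8, 16150001 to 16600000, -1.14 over chromosome 4, 13300001 to 13725000, and -0.770 over chromosome 2, 133925001 to 134350000. Of the 13 regions, 8 lay on chromosome X, some of them overlapping.

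The excess of chromosome X between the times may be a change along the length of the chromosome, such as a different large-scale fold taken up by PC1. Splitting each chromosome into 10 segments accounted for 22.1% of the variance of the 30 min minus 15 min difference on X, above the range over autosomes (3.35 to 13.7%). This leaves most of it unexplained, since the variance within segments was 0.226 on X and at most 0.0690 on an autosome. Whether the X difference lies in the cells or in the libraries was not tested, as each time has 1 sample, of another replicate number, and the instrument used for each is not known.

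The return of bins toward the progenitor state on activation has technical candidates, because the untreated track enters both changes. Short-range noise in that track would average out over 500 kb blocks, but the covariance over 5052 blocks was 0.625 times that over bins at 15 min and 0.581 times at 30 min (0.575 to 0.586 at 30 min when each chromosome was left out), which argues against it as the whole cause. A sequencing batch shared by progenitor and untreated libraries would put these tracks close together. The r of progenitors was higher with the 30 min track than with the untreated one by 0.0236, on 19 of 20 chromosomes (not X). At 15 min the gap was 0.00956, on 14 of 20 chromosomes. Noise lowers r, and the local noise variance was 0.0218 in the untreated track and 0.00595 at 30 min. With an SD of 1.00 in every track, these r also follow from the same covariances as the return. They are therefore no separate test of batch, which stays open at both times. The variance found in the untreated track alone (mean 0.0580, from 0.04997 to 0.0711, overlapping 0.0400 to 0.0611 in progenitors) is computed from the same covariances and decides nothing, so a state lost on activation cannot be told apart from a deviation of this pool without another untreated track. A partial return of neutrophil compartments toward the progenitor layout under calcium is a hypothesis that these data leave open.

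The excess of switches into A at 15 min could come from the place of the zero in standardized values. With the zero of each track moved to the midpoint between its low and high clusters, the ratio of B to A over A to B calls was 54.2. It was 14.4 with the values as deposited, so this move did not end the excess. The median midpoint was 0.227 in the untreated track and 0.0941 at 15 min. The move therefore raised the 15 min track relative to the untreated one. Since the midpoint follows the shape of each track, the test cannot exclude another place of the zero. Quantile normalization brings the excess to an end by its own construction, so whether whole distributions or particular regions changed is not decided by it. Sequencing batch and other differences between re-analysed and activated libraries also stay open here, since they go with the treatment.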

How the results depend on the processing

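Most alternatives were fixed before the data were examined; the moved zero, the running mean and those for the 15 min covariance were chosen after seeing the data. Of 156 recomputed values over 15 results and 15 alternatives, 117 stayed within the limits set (1.5 times for counts, 1 SD over chromosomes for other values), 33 moved beyond them and 6 turned the sign of a value larger than its SD over chromosomes. The contrast change between the times (0.00320%) lay near zero and changed sign under 4 alternatives, counted here with the values that stayed or moved. Scaling by root mean square and keeping all chromosomes moved next to nothing by their construction, and no result moved with even-numbered or odd-numbered bins, no minimum run or the running mean. Switches are given below as percent of analysed bins, B to A then A to B. The cause of each move was not tested unless the construction gives it.

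Quantile normalization gave 0.853% and 0.924% at 15 min, 1.68% and 1.52% at 30 min, 0.815% A to B between the times, 0.7502% shared, and a contrast change of -1.06% between the times; it forces equal numbers of positive bins. Without a size threshold, which admits more bins, values were 2.51% B to A in differentiation, 5.14% and 0.646% at 15 min, 1.497% A to B at 30 min, 1.59% and 3.46% between the times, and 3.07% shared. A threshold of 1 root mean square, which admits fewer, gave 0.319% and 0.744% in differentiation, 0.163% and 0.0288% at 15 min, 0.476% and 0.0984% at 30 min, 0.247% and 0.278% between the times, and 0.00994% shared. Runs of at least 4 bins gave 1.00% B to A in differentiation, and for A to B 0.119% at 15 min, 0.428% at 30 min and 1.10% between the times. On autosomes alone 0.501% went from B to A between the times. With the moved zero, 5.17% and 0.0954% switched at 15 min, and 2.50% were shared. More bins went from B to A than from A to B at 15 and 30 min under every alternative except quantile normalization at 15 min.

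The contrast between A and B domains turned in sign with its definition. With bins taken by sign in the first track it was -6.38% in differentiation and -3.48% between the times. With a common sign in all tracks it was -0.346% in differentiation, 1.20% at 15 min and 1.52% at 30 min, and with the median 0.359%, 2.16% and 2.56%. The covariances of the differentiation change with the 15 min and the 30 min change stayed within 1 SD under the scaling, bin and chromosome alternatives run for them. No paired analysis was possible because progenitor and untreated libraries share replicate numbers in the labels but were pooled into 1 track each, and no result comes from a test. Leaving out replicates was not possible for the same reason. The gene list results were not run. Depth is unknown, so its effect on the calls is not known.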

Other observations

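The values in this part were chosen for description after the data were seen. Untreated domains shorter than 250 kb had the opposite mean sign in another track more often than longer ones, in progenitors and at both times. In progenitors, 49.5% of the neutrophil B domains shorter than 250 kb had a mean above zero, against 10.97% of the longer ones. For A domains shorter than 250 kb, 25.2% had a mean below zero in progenitors, 6.31% at 15 min and 25.0% at 30 min. For longer A domains the shares were 4.48%, 1.25% and 2.71%.

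Switches differed in where they lay. Of the bins that left A in differentiation, 21.7% lay within 100 kb of a sign change in the progenitor track, close to the 17.7% of all bins that do. Of those that entered A, 50.6% did. At 15 min, 66.9% of the bins that entered A lay within 100 kb of a sign change in the untreated track. At 30 min 73.1% did, against 23.7% of all bins. Of the bins that left A, 73.8% did at 15 min and 88.0% at 30 min. A switch has to cross zero, which favours bins with a PC1 near zero in the first track. Such bins tend to lie near its sign changes. A share above that of all bins is therefore partly built into the rule.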
